A study of Homo sapiens with 3 samples.

How the data were processed

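ChIATAC was applied to PC3 DM, a subline of the PC3 prostate adenocarcinoma line that carries the MYC oncogene on double minutes, which are small circles of extrachromosomal DNA (ecDNA). The assay combines proximity ligation with tagmentation, so that it records contacts between DNA segments with an enrichment for open chromatin. The series holds 3 merged libraries, 1 per group: cells with a vector, cells with the perturbation named ecSE1 and cells with the perturbation named ecSEcombo. Per the labels' titles and the series design these are CRISPR-based epigenomic perturbations of ecDNA super-enhancers, and the coordinates of the targeted elements are not given in the sources used here. The control carries the treatment label WT and a title that names a vector, and is called vector throughout. Per the labels' protocols, 700 ng of sgRNA plasmid were transfected, cells were collected 3 days later and fixed with 2% formaldehyde and 2 mM EGS, and chromatin was cut with AluI and HpyCH4V before ligation. Whether the vector cells received the same amount of plasmid is stated by the shared protocol text only.

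Each library has 3 deposited tables on hg38, per the submitters' processing notes. The interchromosomal table holds deposited counts of paired-end tags (PETs) that join clustered anchors, mostly of 500 bp, on different chromosomes, with clusters of a single PET included. The intrachromosomal table holds deposited counts of PETs per loop, with at least 3 PETs in each loop. The aligner, the duplicate handling and the loop and cluster caller are not given in the sources used here. Peaks were called by the authors with MACS2 2.2.7.1, per the submitters' processing notes, in each library separately. In the peak table, the authors' fold column is a ratio, the enrichment at the summit over the local background. The deposited significance columns are −log10 values of p and q, and the authors' score is the −log10 q multiplied by 10 and rounded down. Peak folds, scores and −log10 values are the authors' own. They were used within each list, as in a median or a cut, and no difference in them between libraries was read.

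On chromosomes 1 to 22 and X the interchromosomal (trans) PETs numbered 3146803 in the vector, 4444362 in the ecSE1 and 5130998 in the ecSEcombo library. Trans PETs on the mitochondrial genome were set aside. There were no replicates, so no test between conditions was possible and no p-value is given. Shares carry exact Clopper-Pearson 95% intervals, and ratios carry 95% log-normal counting intervals. These intervals cover counting error only, PCR copies are not independent molecules, and a difference beyond them compares these libraries and not the conditions. A count of 0 allows 3 PETs, which is 9.5e-05% of the vector, 6.8e-05% of the ecSE1 and 5.8e-05% of the ecSEcombo trans PETs.

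The labels give no amplicon coordinates. Bins of 50 kb were kept whose trans PET ends per 1000000 such ends, averaged over the 3 libraries, reached 5 times the median bin. They were joined across gaps of up to 2 bins, and runs under 100 kb were set apart. The run with MYC and the other runs of chromosome 8 within 3 Mb of it were taken as the amplicon: 4 runs and 1100 kb in all. Whether the other runs of chromosome 8 lie on the same ecDNA was not determined, so parts of it may be counted as outside the amplicon. A further 10 runs of chromosome 8 (1650 kb), 20 runs elsewhere (7050 kb) and 44 single bins (2200 kb) also passed the threshold. PETs ending in those other regions stayed in the total of trans PETs. The runs outside chromosome 8 were not used as partners of the amplicon, while single bins outside chromosome 8 stayed in as partners. High coverage stands in for copy number here, which was not measured.

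The amplicon share is the share of trans PETs with an end in the amplicon. Partner ends were divided into those in a peak within 2.5 kb of a gene end, in another peak, and outside peaks, with the union of the 3 peak lists (218413 peaks). For each gene, the share of its trans PETs that joined the amplicon was divided by the same share over all gene windows of the library, and the log2 ratio of a perturbed library over vector was taken after adding 0.5 counts. The gene table (GRCh38.p14) gives no strand, so the transcription start windows that had been planned could not be placed. The gene body extended by 2.5 kb was used instead, windows at the gene ends were added as an alternative, and a planned promoter class became the class of gene-end peaks. Genes on chromosome 8 have no trans contact with the amplicon by construction.

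The genes to be named, the gene lists, the measures and most alternatives were fixed before the data were examined. Named were up to 10 genes per direction and comparison with a 95% interval excluding 0, among protein-coding and lncRNA genes with at least 30 amplicon PETs in the compared libraries, a peak in all 3 libraries and a position outside chromosome 8 and the other high-coverage runs. Also named were the 10 genes with the highest contact in vector, out of 28 with at least 30 amplicon PETs in that library, 2 to 4 members of each list with the most amplicon PETs, the 8q24 genes in the amplicon, and the genes at the 5 loops with most PETs per library inside and outside the amplicon. The 14 lists were MYC targets, ribosomal proteins, mitotic cell cycle, AP-1 and immediate early genes, interferon response, luminal prostate genes, mesenchymal and basal genes, transcriptional coactivators, nuclear body genes, oncogenes, glycolysis and hypoxia, housekeeping genes, markers of other lineages, and 8q24 neighbours. For 13 of them the median log2 ratio was placed among 10000 random lists of the same size matched on trans PETs, and the PETs of all members were also summed. Neighbouring and nested genes share PETs and were not counted as independent. A result on the gene-end peak of 1 list member is not reported here.

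The gene measure was tested on simulated data, with 36447 genes drawn at the depth of these libraries and 200 of them changed. At a fold of 1.5, 2 and 3 it recovered 30.2%, 59.4% and 95.5% of the changed genes with enough PETs for ecSE1 over vector, and 26.5%, 67.9% and 98.3% for ecSEcombo over vector. It called 1.96%, 4.55% and 2.50% of only 51, 44 and 40 unchanged genes with enough PETs for ecSE1 over vector. For ecSEcombo over vector it called 5.00%, 4.76% and 1.69% of 60, 63 and 59 such genes. Counts were drawn gene by gene from a binomial distribution, so PETs shared by neighbouring genes and variation between libraries are not covered by these rates. Of 100 simulated lists of 30 genes, 3% and 6% lay outside the central 95% with no change, 43% and 52% at a fold of 2, and 96% in both comparisons at a fold of 4.

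Alternatives changed the minimum of PETs per cluster, the amplicon threshold, the total, the partner peaks, the gene window, the minimum of amplicon PETs, the depth (thinned to the shallowest library), the random lists, the loop minimum and matching, the peak minimum and matching, and the bin width. Leaving out the bin that holds RNU6-1, taking PETs by their position in peaks, and taking all chromosome 8 runs were added after the data were seen. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Other assays of the study (RNA-seq, ChIP-seq, whole-genome sequencing and others) were not analysed here.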

Results

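Contacts of the MYC ecDNA with the rest of the genome were recorded in PC3 DM cells in 3 merged ChIATAC libraries: vector, ecSE1 perturbation and ecSEcombo perturbation, with 1 library per group and no replicates. The vector library held 3326767 trans PETs, the ecSE1 library 4668485 and the ecSEcombo library 5497854. Of the clusters behind them, 96.0%, 96.1% and 97.2% rested on a single PET. The libraries listed 3242, 4291 and 12521 intrachromosomal loops, and 143191, 157952 and 178189 peaks on chromosomes 1 to 22 and X, in the same order. Because depth and called lists differed between libraries, contacts were compared as shares, with counting intervals.

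The amplicon was seen as 4 chromosome 8 segments (hg38). The segment at 126.3 to 126.65 Mb held LRATD2. The segment at 127.7 to 127.9 Mb held CASC11, MYC and the 5′ part of PVT1, and had 18.8 times the trans PET ends of the median bin. LINC00824 lay at the edge of the segment at 128.55 to 128.65 Mb (23.7 times), and ADCY8, which encodes an adenylate cyclase, reached into the segment at 130.45 to 130.9 Mb (22.7 times). MYC itself, at 127735434 to 127742951 on chromosome 8, encodes the transcription factor amplified on these ecDNAs.

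The first question was whether the perturbed libraries held less contact between the amplicon and other chromosomes. The amplicon took part in 1.36% of trans PETs in vector (95% interval 1.34 to 1.37), in 1.31% in ecSE1 (1.30 to 1.32) and in 1.29% in ecSEcombo (1.29 to 1.30). The share fell to 0.965 times vector in ecSE1 (0.953 to 0.977) and to 0.954 times in ecSEcombo (0.943 to 0.966). For the segment with MYC no fall was detectable over all PETs, at 1.02 times vector in ecSE1 (0.987 to 1.05) and 0.982 times in ecSEcombo (0.954 to 1.01). Without the RNU6-1 bin described below, its share in ecSEcombo was 0.865 times vector among PETs with both ends in peaks (0.801 to 0.934). It was 0.887 times with 1 end in a peak (0.854 to 0.922). The values in peaks are shares within parts of the PETs that grew in ecSEcombo, as given further below, and not counts per trans PET. The other high-coverage runs of chromosome 8 fell further, to 0.924 (0.914 to 0.935) and 0.891 times (0.881 to 0.901), led by the run at 133.65 to 133.85 Mb with LINC03024, at 0.839 (0.820 to 0.858) and 0.782 times (0.764 to 0.80). The 9 others, pooled after these values were seen, fell to 0.955 (0.943 to 0.968) and 0.930 times (0.918 to 0.942). High-coverage runs of chromosome 10 beyond 60 Mb fell as well, to 0.957 (0.948 to 0.967) and 0.945 times (0.936 to 0.955).

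A single 50 kb bin of chromosome 15 with RNU6-1, the U6 small nuclear RNA gene at 67839939 to 67840045, took 0.530% of trans PETs in vector, 3.39% in ecSE1 and 5.92% in ecSEcombo. That rose to 6.41 times vector in ecSE1 (6.31 to 6.51) and to 11.2 times in ecSEcombo (11 to 11.3). Without its PETs the amplicon ratios were 0.978 (0.966 to 0.991) and 0.979 (0.967 to 0.991). Among clusters of at least 3 PETs the amplicon share was higher in the perturbed libraries, at 1.2 times vector in ecSE1 (1.13 to 1.29) and 1.85 times in ecSEcombo (1.74 to 1.98). With the RNU6-1 bin left out the same clusters gave 0.979 (0.912 to 1.05) and 0.772 times (0.706 to 0.844).

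**Figure D1:**
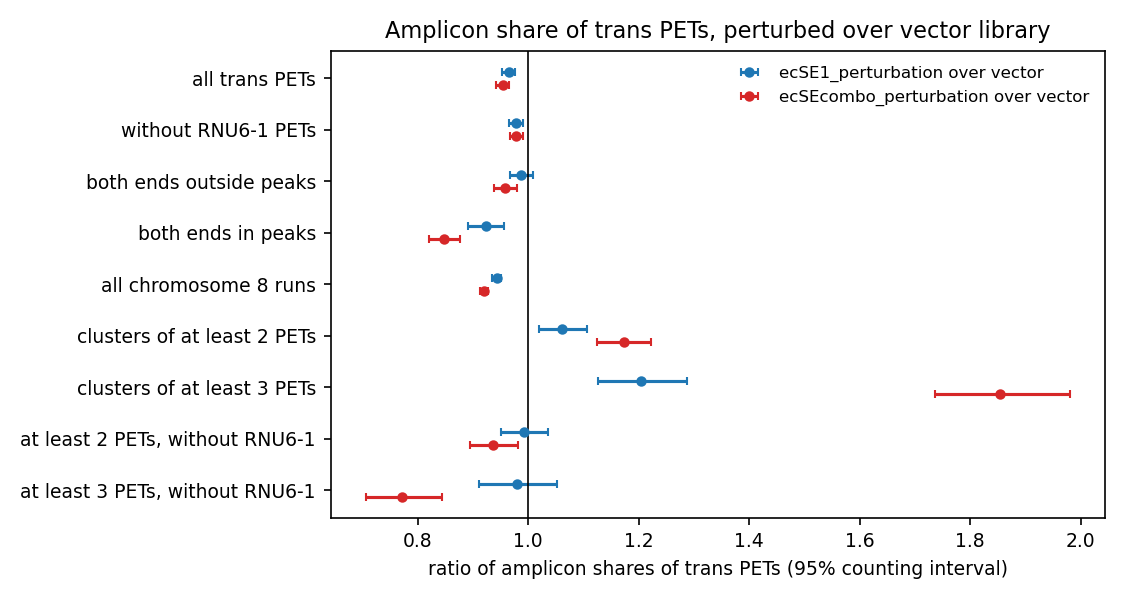
Ratio of the amplicon share of trans PETs in each perturbed library over vector (x axis, no unit), for all PETs and for 8 other ways of counting; points are ratios, bars are 95% counting intervals, and the line marks 1. The ratio for all PETs lies at 0.965 and 0.954, and clusters of at least 3 PETs reach 1.85 for ecSEcombo only while the RNU6-1 bin is kept.

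Trans contacts of the genes that lie in or reach into the amplicon moved in different directions. Whole genes were counted, and PVT1 (to 128101256), LINC00824 (from 128405269) and ADCY8 (to 131040909) extend beyond the segments. Their ratios thus mix DNA inside and outside the amplicon. MYC had 1203 trans PETs in vector, 1867 in ecSE1 and 2005 in ecSEcombo, and per trans PET of the library it rose to 1.10 times vector in ecSE1 (1.02 to 1.18) and stood at 1.02 times in ecSEcombo (0.952 to 1.10). PVT1, the long noncoding RNA gene beside MYC, rose to 1.05 times vector in both libraries (1.01 to 1.09 in each). Its miRNA MIR1204 rose to 1.24 times in ecSE1 (1.12 to 1.38) and stood at 1.08 times in ecSEcombo (0.969 to 1.2). CASC11 rose to 1.08 times in ecSE1 (1.00 to 1.16, with the lower bound above 1) and fell to 0.918 times in ecSEcombo (0.855 to 0.985). ADCY8 fell to 0.932 times (0.891 to 0.975) and 0.878 times (0.840 to 0.918). LRATD2 stood at 1.10 times in ecSE1 (0.984 to 1.24) and rose to 1.2 times in ecSEcombo (1.08 to 1.35). LINC00824 stood at 1.02 (0.956 to 1.09) and 1.04 times (0.979 to 1.11). These ratios are per trans PET with the RNU6-1 bin included; without it CASC11 was at 0.953 times in ecSEcombo (0.887 to 1.02), so its fall was no longer distinguished, LINC00824 rose to 1.07 times in ecSEcombo (1.01 to 1.14), and the lower bound of LRATD2 in ecSE1 came to just above 1, at 1.12 times (1.00 to 1.26).

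Bins of 25 kb gave a finer view, as shares of all amplicon ends. The bin with MYC and the end of CASC11 rose by a log2 ratio of 0.17 in ecSE1 (0.09 to 0.26), and the next bin, at 127750001 to 127775000, fell in both libraries, at −0.18 (−0.29 to −0.06) and −0.24 (−0.36 to −0.13). A PVT1 bin at 127850001 to 127875000 rose by 0.39 in ecSEcombo (0.24 to 0.55), and a bin without an annotated gene at 126425001 to 126450000 rose by 0.27 in ecSE1 (0.12 to 0.41) and 0.30 in ecSEcombo (0.16 to 0.45). Of 44 bins, 5 were higher and 8 lower in ecSE1, and 11 were higher and 14 lower in ecSEcombo, where counting error alone would give 1.1 in each direction. Bin shares add up to a fixed total, so a rise in some bins lowers others.

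**Figure D2:**
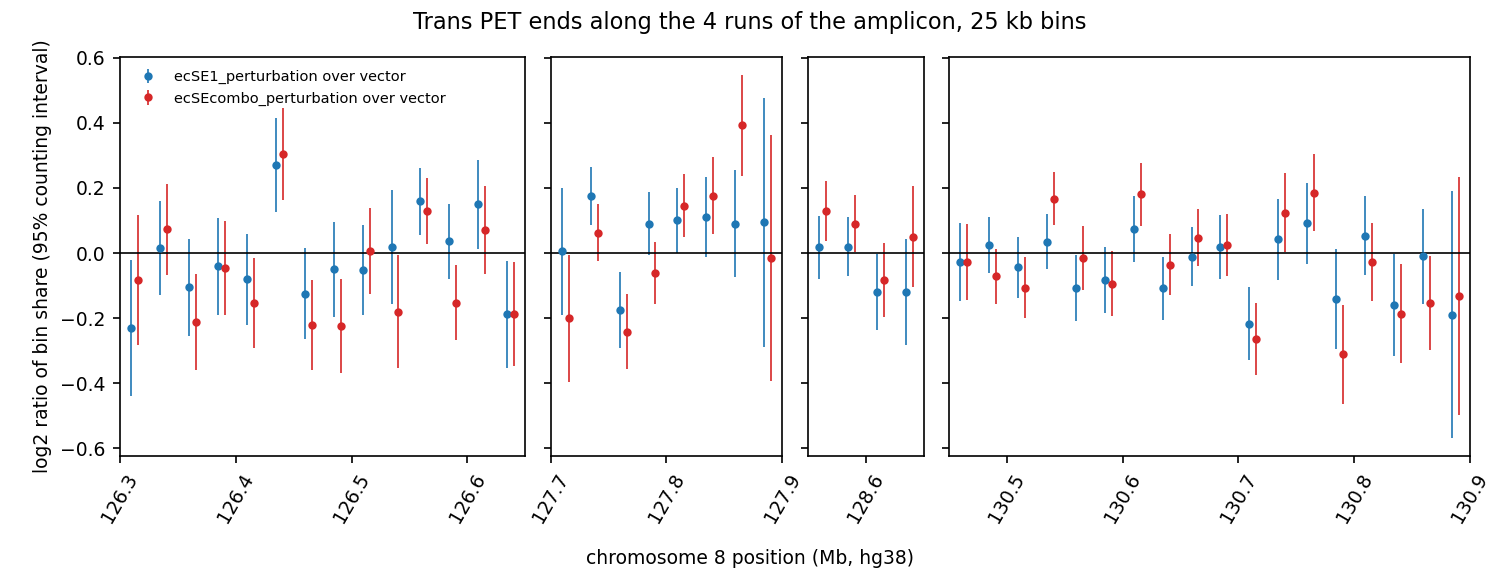
log2 ratio of the share of amplicon trans PET ends in each 25 kb bin, perturbed over vector (y axis), along the 4 chromosome 8 segments (x axis, Mb, hg38), with 95% counting intervals. Values run from −0.23 to 0.27 for ecSE1 and from −0.31 to 0.39 for ecSEcombo, the latter in PVT1.

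The kind of partner site made little difference to contact with the amplicon. In vector 0.736% of trans ends in gene-end peaks joined it, 0.752% of ends in other peaks and 0.726% of ends outside peaks. Gene-end peaks stood at 1.01 times the level outside peaks in vector (0.969 to 1.06) and in ecSE1 (0.982 to 1.05), and at 1.06 times in ecSEcombo (1.03 to 1.09). Other peaks were at 1.04 times in each library, with an interval of 1.01 to 1.06 in vector, 1.02 to 1.06 in ecSE1 and 1.02 to 1.06 in ecSEcombo, but at 0.878 times in ecSEcombo in clusters of at least 2 PETs, with or without the RNU6-1 bin. In clusters of at least 2 PETs the gene-end ratio was 2.15 in ecSE1 and 3.36 in ecSEcombo, and without the RNU6-1 bin those values were 0.939 and 1.05.

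Contact with the amplicon was unequal between chromosomes. Chromosome 11 had the highest share in vector, 1.07% of its trans ends (1.03 to 1.11), against a median chromosome at 0.648%, and chromosome 10 had 1.01% (0.981 to 1.05). Chromosome 11 fell to 0.875 times vector in ecSE1 (0.834 to 0.918) and 0.877 times in ecSEcombo (0.837 to 0.919). The stretch at 75.0 to 79.0 Mb described below held 1240 of its 3003 amplicon PETs in vector, on 16610 of its 280509 trans ends. It held 1351 of 3712 in ecSE1 and 1610 of 4212 in ecSEcombo. The high share and the fall of this chromosome therefore partly restate those of the stretch. In ecSE1, 3 of 22 chromosomes were lower and 0 higher. In ecSEcombo, 8 were lower and 1 higher, with 0.55 per direction given by counting error around a ratio of 1. The higher one was chromosome 15, which holds RNU6-1, and without that bin 4 were lower and 0 higher (1 and 0 in ecSE1). These ratios were not divided by the fall of the whole amplicon share, to 0.965 and 0.954 times vector. The counts of lower chromosomes therefore partly restate that fall, as with chromosome 1 at 0.945 times in ecSEcombo (0.907 to 0.986).

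Of the 28 genes with at least 30 amplicon PETs in vector that met the other conditions, those in closest contact with the amplicon lay on the long arm of chromosome 11, where 9 of the leading 10 were found between 75.0 and 79.0 Mb. NARS2, a mitochondrial asparaginyl-tRNA synthetase, joined the amplicon 20.2 times as often as an average gene (16.8 to 24.3). The readthrough gene NDUFC2-KCTD14 stood at 18.7 times (14.6 to 23.9), the signalling adaptor GAB2 at 17.8 times (15.4 to 20.4), AAMDC at 16.9 times, the Integrator subunit gene INTS4 at 15.4 times, the chromatin remodelling gene RSF1 at 14.6 times and EMSY at 12.9 times. ARRB1, which encodes a beta-arrestin, was at 9.69 times and the ceramidase gene ACER3 at 8.44 times. JCAD on chromosome 10 was at 8.98 times (6.52 to 12.4). NARS2 stood at 13.7 times in ecSE1 and 16.3 times in ecSEcombo, and GAB2 at 15.1 and 19.3 times. The whole 75.0 to 79.0 Mb stretch, delimited after its values were seen, was at 10.2 times the average in vector (9.68 to 10.8), 8.57 in ecSE1 (8.13 to 9.03) and 9.00 in ecSEcombo (8.58 to 9.44). Its log2 ratio to vector was −0.26 (−0.36 to −0.15) in ecSE1 and −0.18 (−0.29 to −0.08) in ecSEcombo. This stretch was not continuous, as 7 of its 8 bins of 500 kb reached 5 times the average in vector. The bin between 75.5 and 76 Mb stood at 1.46 times in vector (0.884 to 2.42), 0.885 in ecSE1 and 0.856 in ecSEcombo. A stretch of chromosome 10 at 29.0 to 30.5 Mb stood at 8.26 times in vector, 7.62 in ecSE1 and 6.62 in ecSEcombo.

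**Figure D3:**
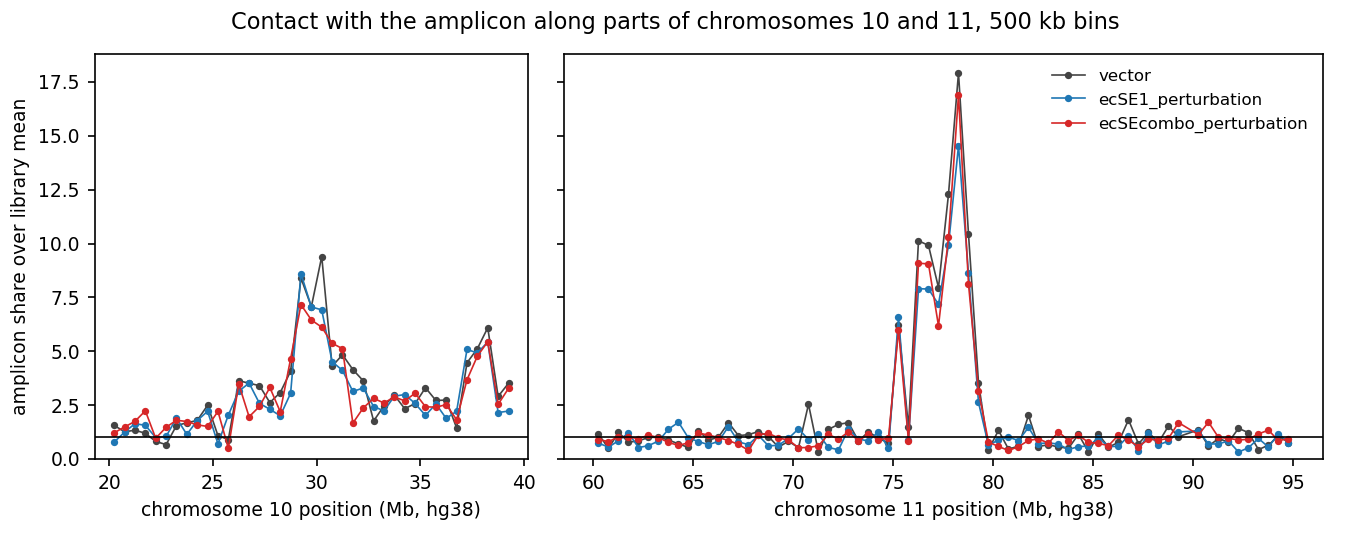
Share of trans ends that join the amplicon over the library mean (y axis, no unit) in 500 kb bins of parts of chromosomes 10 and 11 (x axis, Mb, hg38) in the 3 libraries, with a line at 1. The chromosome 11 stretch between 75.0 and 79.0 Mb averages 10.2 in vector, and the chromosome 10 stretch at 29.0 to 30.5 Mb averages 8.26.

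Among genes with at least 30 amplicon PETs, 167 could be compared between ecSE1 and vector. COL19A1, a collagen gene of chromosome 6, rose by a log2 ratio of 1.00 (0.10 to 1.90), from 13 to 34 amplicon PETs. Lower were ACER3-AS1 (−1.68, interval −2.71 to −0.65), the centriole gene CEP128 (−1.42, −2.36 to −0.47), AUTS2 (−1.25, −2.10 to −0.40), the mitochondrial peptidase gene IMMP2L (−1.21, −2.26 to −0.17) and GVQW3 (−1.10, −2.04 to −0.17). LINC02549 (−1.07), the synaptic scaffold gene SHANK2 (−1.06), GALNTL6 (−1.02), KCTD14 (−0.97) and ACER3 (−0.94, −1.63 to −0.25) were also lower. ACER3-AS1, ACER3, GVQW3 and KCTD14 belong to the 75.0 to 79.0 Mb stretch, and ACER3-AS1 shares PETs with ACER3. In total 1 gene was higher and 16 lower, where counting error alone would give 4.18 in each direction. At equal depth 10 of the 16 lower genes and the 1 higher gene kept their call among 115 genes. Scaled to all trans PETs, 15 of the 16 kept it and COL19A1 did not, at 0.86 (−0.05 to 1.76); the median over the compared genes moved from 0.06 to −0.08 with that scaling.

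Between ecSEcombo and vector, 187 genes could be compared. CAMTA1, a calmodulin-binding transcription activator gene, rose by 1.67 (0.45 to 2.90), from 6 to 29 amplicon PETs, LHFPL3 rose by 1.51 (0.27 to 2.75) and ROBO2, an axon guidance receptor gene, by 0.87 (0.10 to 1.64). CALN1 (−1.25, interval −2.29 to −0.21), CEP128 (−1.21, −2.08 to −0.33), LINC02549 (−1.11, −2.04 to −0.19), TTC6 (−1.07, −1.91 to −0.23) and AUTS2 (−0.93, −1.72 to −0.14) were lower. So were CA10 (−0.97), the protein kinase C gene PRKCE (−0.96), JCAD (−0.67), NDUFC2-KCTD14 (−0.59) and the teneurin gene TENM4 (−0.36, −0.68 to −0.04). The total was 3 higher and 10 lower, with 4.68 in each direction given by counting error, so the number of higher genes was within what counting error gives in both comparisons. At equal depth 3 of the 10 lower genes and 1 of the 3 higher ones kept their call among 119 genes. Scaled to all trans PETs, 10 of the 10 and 2 of the 3 kept it, ROBO2 was at 0.74 (−0.03 to 1.51), and the median over the compared genes moved from 0.01 to −0.10. With windows at the gene ends, 39 and 42 genes could be compared at a minimum of 10 PETs, and 2 of the 16 and 1 of the 10 lower genes kept their call.

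The fixed gene lists asked whether the amplicon met functional groups of genes more or less often. Each list had between 15 and 109 amplicon PETs per comparison, and 0 members passed the interval singly. The summed PETs of the oncogene list rose by a log2 ratio of 0.73 in ecSE1 (0.12 to 1.35; 30 to 70 PETs) and 0.63 in ecSEcombo (0.02 to 1.23; 79 PETs), with GLI2 at 4, 9 and 10 PETs in the 3 libraries and CDK6 at 0, 7 and 7. AP-1 and immediate early genes rose by 1.91 in ecSEcombo (0.18 to 3.64), from 3 to 23 PETs, and had 1.43 in ecSE1 (−0.40 to 3.25). Markers of other lineages, genes of blood, liver, muscle and brain, rose by 0.85 in ecSE1 (0.13 to 1.56), led by the neuronal RBFOX3 with 9 and 24 PETs, and had 0.46 in ecSEcombo (−0.28 to 1.2). With windows at the gene ends the sums that passed held 0: 0.71 and 0.74 for oncogenes, 1.87 for AP-1 genes in ecSEcombo and, with the direction turned, −0.10 for other lineages in ecSE1 (−1.43 to 1.24). Thus 2 of 13 lists passed in each comparison, with 0.65 given by counting error.

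The MYC target list, nucleolar and growth genes among them, had 11, 13 and 15 amplicon PETs in the 3 libraries, and its summed log2 ratio was −0.35 in ecSE1 (−1.51 to 0.80) and −0.38 in ecSEcombo (−1.50 to 0.74), or −1.63 in ecSEcombo with windows at the gene ends (−3.24 to −0.02). The summed interval also held 0 for each of the other 9 lists. In ecSE1 and ecSEcombo these gave 0.55 and 0.34 for ribosomal proteins, 0.39 and −0.02 for the mitotic cell cycle, 0.01 and 0.14 for the interferon response, 0.15 and −0.09 for luminal prostate genes, 0.02 and 0.15 for mesenchymal and basal genes, 0.09 and −0.04 for transcriptional coactivators, −0.50 and −0.65 for nuclear body genes, 0.47 and 0.70 for glycolysis and hypoxia, and 0.62 and −0.13 for housekeeping genes. Single members had few PETs: P4HA1 of the hypoxia list had 4, 13 and 13, MED13L of the coactivators 7, 14 and 8, TP63 of the basal genes 8, 13 and 9, and NEAT1 of the nuclear body genes 3 in each library. TFB2M and IPO4 of the MYC targets had 1, 1 and 2 and 1 in each library, RPL27 and RPL6 of the ribosomal proteins 0, 3 and 0 and 0, 0 and 3, BUB1B and KIF11 of the mitotic genes 2, 2 and 1 and 0, 2 and 3. ATF3 and EGR2 of the AP-1 list had 1, 3 and 6 and 0, 2 and 3, RIGI and OAS2 of the interferon response 4, 1 and 3 and 1, 3 and 2, and ZBTB16 and PMEPA1 of the luminal prostate list 8, 5 and 4 and 1, 8 and 2. ZEB1 of the mesenchymal genes had 6, 5 and 6, MED13 of the coactivators 3, 5 and 5, H2BC5 of the nuclear body genes 1, 2 and 2, HK1 of the glycolysis list 4, 7 and 9, PSMB2 and EEF1A1 of the housekeeping genes 2, 2 and 1 and 0, 3 and 0, and VWF, an endothelial marker, 5, 5 and 2.

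By the median of the members, 0 lists lay outside the central 95% of matched random lists in ecSE1 and 3 in ecSEcombo. These were MYC targets (median −0.84, percentile 1.95), nuclear body genes (−0.88, percentile 1.65) and mesenchymal and basal genes (0.50, percentile 97.7), and nuclear body genes alone remained without the RNU6-1 bin. With windows at the gene ends the percentiles were 1.81 for MYC targets, 5.19 for nuclear body genes and 46.7 for mesenchymal and basal genes. Scaled to all trans PETs the last list was at 98.6, and the first 2 had a median of −0.71, equal to that of their random lists, so their percentile was set by ties. With that scaling the median of the AP-1 genes in ecSEcombo, negative otherwise, was 0.46 at percentile 98.6. Random lists matched to the MYC targets also had a median below 0, at −0.50. Medians are taken after the added count, which weighs on genes with few PETs and a deeper perturbed library, and they were below 0 while sums were above 0 for ribosomal proteins (−0.78), AP-1 genes (−0.29), the interferon response (−0.41), glycolysis and hypoxia (−0.62) and other lineages (−0.23) in ecSEcombo.

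Chromosome 8 also held the loops with most PETs. A loop of 4598 kb joined FER1L6 to LINC00824 with 142 PETs in vector, 145 in ecSE1 and 276 in ecSEcombo, and a loop of 1289 kb joined the segment with LRATD2 to PVT1 with 42, 55 and 85 PETs. The region of MYC and CASC11 was joined to PVT1 over 117 kb by 30, 35 and 107 PETs and to TG, the thyroglobulin gene, by 9, 41 and 31. The loop from TG to LINC03024 had 89, 38 and 62 PETs. Spans are distances on hg38, and how these regions are arranged on the ecDNA was not determined. Whether such PETs mark chromatin contact or a junction between segments was not tested. These loops were named as leading loops of at least 1 library and PETs outside called loops were not counted, while the loop lists held 13821, 17047 and 51714 PETs in all, so no change between libraries was read from these counts.

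Loops inside the amplicon made up 10.1% of loops in vector (9.13 to 11.2), 8.60% in ecSE1 (7.78 to 9.48) and 4.78% in ecSEcombo (4.42 to 5.17). The loop lists were called separately, with 4.26, 3.97 and 4.13 PETs per loop, 5.13, 6.86 and 23.8 Mb of anchors and a median span of 90.8, 77.9 and 31.5 kb, so the shares move with what was called. With the same number of loops taken from each library the shares were 10.1%, 6.57% and 8.24%, and with loops of at least 5 PETs they were 13.8%, 18.5% and 10.7%. Of the vector's amplicon loops, 45.0% were found in ecSE1 (39.5 to 50.5) and 57.8% in ecSEcombo (52.2 to 63.1), against 7.35% and 15.3% of the loops outside the chromosome 8 runs. This rested on the matching: with anchors widened by 5 kb 84.2% and 90.9% of the amplicon loops were found, and with the same number of loops 35.3% and 48.3%. In vector 329 loops lay within the 1100 kb of the amplicon and 2498 outside the chromosome 8 runs. Anchors overlap more easily where loops are that dense, and the rate of overlap by position alone was not computed. The contrast therefore does not show that amplicon loops were better kept.

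Open chromatin at the amplicon was largely shared. The amplicon held 322 peaks in vector, 327 in ecSE1 and 334 in ecSEcombo, and 85.1% of the vector peaks were found in ecSE1 (80.7 to 88.8) and 87.0% in ecSEcombo (82.8 to 90.4). Genome-wide the values were 80.1% (79.9 to 80.4) and 83.5% (83.3 to 83.7), with 47.3, 52.5 and 61.3 Mb covered by peaks and a median fold of 5.23, 5.46 and 5.43. A vector peak at 127742493 to 127742793, at the 3′ end of MYC, had no counterpart in ecSE1 or ecSEcombo, and a MYC peak of ecSEcombo at 127738405 to 127738738 had none in vector. A gene-end peak was present in all 3 libraries for 31 of 32 MYC targets, 32 of 32 ribosomal protein genes, 20 of 20 mitotic genes, 20 of 20 AP-1 genes and 22 of 22 coactivators, and for 10 of 19 luminal prostate genes and 17 of 32 markers of other lineages. Of 34 genes of the 8q24 list, 23 had one in vector, 26 in ecSE1 and 27 in ecSEcombo.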

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

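The tests on mitochondrial partners, on the amplicon ratio without RNU6-1 and on the chromosome 10 runs were chosen only after the results they measure had been seen; the tests on the flanks and the amplicon partners of RNU6-1 and on the leading anchors of the 11q stretch were written before. Mitochondrial DNA is a signal that no comparison used: 6.46% of all trans PETs in ecSEcombo joined it (6.44 to 6.48), against 5.05% in vector (5.03 to 5.08) and 4.49% in ecSE1 (4.47 to 4.50), which is 1.28 times vector in ecSEcombo (1.27 to 1.29) and 0.888 times in ecSE1 (0.882 to 0.894).

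The trans PETs at RNU6-1 numbered 16610 in vector, 150731 in ecSE1 and 303630 in ecSEcombo. Random ligation in solution that takes in mitochondrial DNA at its usual rate is argued against. Mitochondrial DNA was 0.363 times as frequent among RNU6-1 partners in ecSEcombo as among other trans ends (0.352 to 0.375), where that explanation needs 1. The deficit was also present in vector, at 0.324 times (0.275 to 0.382), and in ecSE1, at 0.336. Only mitochondrial partners were measured by this test, so random ligation among nuclear DNA stays open. The amplicon share of RNU6-1 partners, given next, was near the expected one, as such ligation would give. A preference of RNU6-1 for the amplicon needed more than 1.2 times the expected share and the value was 1.02 (0.976 to 1.06); the bound of at most 1 set beforehand for the opposite outcome was not met, and reading the interval against 1.2 was decided after the value was seen. Reads of the transfected sgRNA plasmid placed at RNU6-1 stay open as a candidate explanation, since ends within 50 kb of the gene but outside its 2 kb surroundings stood at 0.975 times vector in ecSEcombo (0.801 to 1.19), while a locus that gains contacts would carry its neighbours. Plasmids for sgRNAs often carry a U6 promoter, but the plasmid sequence was not available, and a gain confined to the gene itself, as an effect of the perturbation, was not tested.

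As the whole cause of the lower amplicon share in the perturbed libraries, dilution by RNU6-1 PETs needs a ratio of 1 without them. Without them ecSEcombo still stood at 0.979 times vector (0.967 to 0.991), which is below 1 by counting error only. By the same measure the chromosome 10 runs stood at 0.975 pooled and from 0.906 to 1.15 singly, with 1 library per group. A remainder this small does not settle whether dilution was the whole cause. Divided by the ratio of the chromosome 10 runs, the amplicon ratio in ecSEcombo was 1.00 without the RNU6-1 bin (0.989 to 1.02), but this joined parts that differed. It was 0.917 for PETs with both ends in peaks (0.875 to 0.961), 0.922 with 1 end in a peak (0.902 to 0.943) and 1.03 with no end in a peak (1.01 to 1.06), and in ecSE1 0.972 (0.925 to 1.02), 0.965 (0.943 to 0.988) and 1.03 (1.01 to 1.06). Each rests on shares within its part, and the parts changed in size. PETs with both ends in peaks went from 129343 of 3130129 in vector to 299988 of 4827248 in ecSEcombo, and their amplicon PETs from 5032 to 9896. With 1 end in a peak they went from 977829 to 1733952, and with none from 2022957 to 2793308. With both ends in peaks the lower share thus came with more amplicon PETs per trans PET of the library. The 9 single chromosome 10 runs spread in ecSEcombo from 0.825 to 1.39, from 0.921 to 1.17 and from 0.961 to 1.13 of their pooled value in these parts. In ecSE1 they spread from 0.886 to 1.26, from 0.969 to 1.03 and from 0.959 to 1.07. The amplicon's 0.965 with 1 end in a peak lay below the lowest of those ecSE1 runs, but its interval reached above that run. A fall shared by high-coverage regions therefore stays open for the amplicon. The same division put the 9 smaller other runs of chromosome 8 at 0.980 over all PETs (0.964 to 0.996). They stood at 0.904 with both ends in peaks, 0.913 with 1 end and 1.02 with none, and such a fall stays open too. The run at 133.65 to 133.85 Mb stood at 0.822 over all PETs (0.802 to 0.842), below the lowest single chromosome 10 run at 0.929. This cannot decide on a shared fall there, as those chromosome 10 runs reached at most 6.46 times the median bin, against 29.7. From vector to ecSEcombo that run's depth-scaled trans ends went from 2120 to 1658. Runs of similar coverage fell from 1501 to 808 on chromosome 4 (49.05 Mb) and from 1226 to 673 on chromosome 5 (49.6 Mb). Another fell from 1392 to 761 on chromosome 10 (41.85 Mb). A single bin of similar coverage on chromosome 3 (93.45 Mb) rose from 434 to 477, with 99.9% of its ends in 1 kb in vector. On chromosome 8, amplicon segments of similar coverage went from 756 to 753 (128.55 Mb) and from 3303 to 3130 (130.45 Mb). The single bin with TG (132.85 Mb, 28.7 times the median bin) fell from 499 to 392. All these regions were matched on coverage only, so they do not decide on a shared fall either. An effect of the perturbation and a change in copy number, which was not measured, both stay open, untested.

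The 11q stretch at 75.0 to 79.0 Mb joined the amplicon 10.2 times as often as the average in vector. Reads that fit both places and pile up at a few sites are argued against by the 10 leading anchors of 500 bp, which held 3.31% of its amplicon PETs, where that explanation needs at least 50%. A junction between 11q and amplified chromosome 8 DNA and a preferred nuclear position beside the ecDNA were not tested. The stretch was high in all 3 libraries, so the design gives no biological group to set against these.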

How the results depend on the processing

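Alternatives around the RNU6-1 bin, all chromosome 8 runs, position in peaks and windows at gene ends were chosen after seeing the data; the others were planned. No paired analysis was possible because each group has 1 library. Planned windows at transcription starts were not run, as the gene table gives no strand. Single genes (at least 30 PETs) and lists (15 to 109 PETs) rest on few PETs, and loops and peaks were called in each library separately. Of the alternative values of the main counts and ratios, 66 stayed within the interval or within 1.5 times of the reported count. A further 62 moved beyond that and 6 reversed, and these are the values given here. For single named genes and lists, 174 values kept their call, 18 lost it, 10 gained one and 1 reversed. Among those lost, MYC targets and nuclear body genes in ecSEcombo scaled to all trans PETs only tied with their random lists. Except where a construction is named, the cause was not tested.

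The amplicon share over vector (ecSE1, then ecSEcombo) reversed in clusters of at least 2 PETs (1.06, 1.17) and at least 3 PETs (1.2, 1.85). Without the RNU6-1 bin these became 0.992 and 0.937, and 0.979 and 0.772, so that bin carries the reversal. With all PETs and that bin left out the ratios were 0.978 and 0.979. With both ends in peaks they were 0.924 and 0.848, with 1 end in a peak 0.933 and 0.859, with both ends outside peaks 0.988 in ecSE1, and with all chromosome 8 runs 0.943 and 0.920. The ratios by position in peaks compare shares within those PETs, whose part of the library changed. Clusters counted once each gave 0.940 in ecSEcombo.

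For partner class, gene-end peaks over no peak in clusters of at least 2 PETs reached 2.15 in ecSE1 and 3.36 in ecSEcombo, against 0.939 in ecSE1 without the RNU6-1 bin. Other peaks reversed in ecSEcombo clusters of at least 2 PETs, at 0.878 with that bin and 0.878 without it. A gene-end window of 1 kb gave 1.09 in ecSEcombo.

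Genes called moved as follows. With a minimum of 50 PETs, 0 were higher and 6 lower in ecSE1, and 1 higher and 4 lower in ecSEcombo, as fewer genes were tested. Thinned to the shallowest library, 2 were higher in ecSE1 and 4 lower in ecSEcombo. Scaled to all trans PETs, 19 were lower in ecSEcombo. In clusters of at least 2 PETs, 10 were lower in ecSE1, but the median over the compared genes was −1.41 there and −0.62 in ecSEcombo, so lower calls say little. At gene ends, 0 were higher and 3 lower in ecSE1, and 3 lower in ecSEcombo.

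Lists outside the central 95% numbered 1 in ecSE1 and 5 in ecSEcombo with unmatched random lists, 1 in ecSE1 at gene ends, and 1 in ecSEcombo without the RNU6-1 bin. By summed PETs instead of medians, 2 passed in ecSE1. At gene ends the sums that had passed held 0: oncogenes at 0.71 in ecSE1 (−0.77 to 2.2) and 0.74 in ecSEcombo (−0.69 to 2.18), AP-1 genes at 1.87 in ecSEcombo (−0.25 to 3.98), and other lineages at −0.10 in ecSE1 (−1.43 to 1.24), on 18 to 22 PETs; MYC targets then fell by 1.63 in ecSEcombo (−3.24 to −0.02). The median of mesenchymal and basal genes in ecSEcombo reversed at gene ends, to −0.69.

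Loops of at least 5 PETs gave amplicon shares of 13.8%, 18.5% and 10.7% (vector, ecSE1, ecSEcombo), and 14.7% and 22.8% of vector loops found in ecSE1 and ecSEcombo. The same number of loops per library gave 6.57% and 8.24% in ecSE1 and ecSEcombo, with 9.07% and 13.0% found. Anchors widened by 5 kb gave 24.8% and 37.0% found. Of the vector's amplicon loops 84.2% and 90.9% were found with widened anchors, 35.3% and 48.3% with the same number of loops, and 44.7% and 69.9% with loops of at least 5 PETs.

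Vector peaks found in ecSE1 and ecSEcombo were 85.8% and 89.2% at a −log10 q of at least 10, 77.8% and 78.2% with equal numbers of peaks, and 71.3% and 71.4% at a reciprocal overlap of 50%. Amplicon peaks found were 89.2% in ecSE1 at that −log10 q, 82.0% in ecSEcombo with equal numbers, and 74.8% and 70.2% at that overlap.

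Along all chromosome 8 runs, 7.27% of bins were lower in ecSE1. In clusters of at least 2 PETs, 11.4% of amplicon bins were higher and 18.2% lower in ecSEcombo, and 3 chromosomes were higher in ecSE1. Without the RNU6-1 bin, 1 chromosome was lower in ecSE1, and 4 were lower and 0 higher in ecSEcombo.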

Other observations

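The sites and genes described here were singled out only after the data were seen, and no explanation was tested. Single bins were kept on the mean coverage of the 3 libraries. Of these 44 bins, 14 had an interval above 1 and 9 an interval below 1 in both perturbed libraries. The 5 above 3 times vector in both were RNU6-1 and 4 others. In vector the 4 others had 13.2 (CSMD1), 15.6 (chromosome 9), 21.9 (COL25A1) and 42.4 (FARS2) depth-scaled trans ends. The median bin had 15.6 and RNU6-1 had 2649. Those 4 thus passed the threshold through the perturbed libraries, so the selection itself required a rise over vector in at least 1 of them. How many bins this selection alone would place above or below 1 was not computed. A site in CSMD1, a large gene of chromosome 8 at 3.75 to 3.8 Mb, had 83 trans ends in vector, 3305 in ecSE1 and 2303 in ecSEcombo, which is 28.2 times vector (22.7 to 35.1) and 17.0 times (13.7 to 21.2) per trans PET. A site without an annotated gene on chromosome 9, at 103.4 to 103.45 Mb, rose to 10.4 times (8.45 to 12.7) and 8.35 times (6.80 to 10.2). FARS2, which encodes a mitochondrial phenylalanyl-tRNA synthetase, rose at 5.7 to 5.75 Mb of chromosome 6 to 5.82 times (5.13 to 6.61) and 8.14 times (7.19 to 9.22). COL25A1, a collagen gene of chromosome 4, rose to 4.65 times (3.89 to 5.56) and 6.58 times (5.52 to 7.83). The ends were concentrated in a small part of each bin: the leading 1 kb held 96.1% of the CSMD1 ends, 91.5% of the chromosome 9 ends, 94.7% of the FARS2 ends and 85.7% of the COL25A1 ends in ecSE1, against 6.02%, 7.14%, 62.2% and 44.9% in vector.

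Of 27 genes of the 8q24 list outside the amplicon segments, 2 were higher and 1 lower in ecSE1 and 3 higher and 4 lower in ecSEcombo, with 0.675 in each direction given by counting error. Without the RNU6-1 bin these were 3 and 0, and 4 and 2, with POU5F1B in ecSE1 and CASC8 and GSDMC in ecSEcombo no longer distinguished. Trans PETs of NSMCE2, a SUMO ligase gene centromeric of MYC, rose to 1.09 times vector in ecSE1 (1.01 to 1.19) and 1.22 times in ecSEcombo (1.13 to 1.32). SQLE, which encodes squalene epoxidase of sterol synthesis, was at 1.08 times in ecSE1 (0.814 to 1.43) and rose to 1.37 times in ecSEcombo (1.05 to 1.79). TRIB1, a pseudokinase gene, rose to 1.27 times in ecSE1 (1.01 to 1.58) and was at 1.19 times in ecSEcombo (0.953 to 1.48). CASC8 was at 0.941 times in ecSE1 (0.844 to 1.05) and fell to 0.890 times in ecSEcombo (0.80 to 0.990), and POU5F1B fell to 0.515 times in ecSE1 (0.270 to 0.980) and was at 0.808 times in ecSEcombo (0.464 to 1.41) on 22, 16 and 29 PETs. CYRIB rose to 1.18 times in ecSEcombo (1.06 to 1.31), while CCDC26 fell to 0.895 times (0.826 to 0.969), GSDMC to 0.854 times (0.732 to 0.997) and MIR1205 to 0.383 times (0.174 to 0.845) in that library, with intervals that held 1 in ecSE1.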
